A study of Saccharomyces cerevisiae with 15 samples.

How the data were processed

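ChIP samples from budding yeast were hybridised to Agilent tiling arrays with 243504 features each. Per the labels, Pol II was precipitated with antibody 8WG16, Top2 with an antibody from TopoGEN and histone H3 with an antibody from Abcam, and the strains were W303-1a (wild type), AMR51 (top1), RS191 (top2-ts) and RS192 (top1,top2-ts), kept for 1 h at 37 C. Histone H4 was depleted in strain UKY403 by 6 h in glucose, with galactose as the control, and Pol II was inactivated in strain Z460 (rpb1-1) with Z579 (RPB1) as the control. Samples were grouped by the strain and antibody in the labels: 7 groups of ChIP over input with 2 arrays each, and 6 direct comparisons with 1 array each. The labels carry no replicate numbers that pair arrays of different strains, so arrays were paired only by the scan day in the file headers, as an alternative. A further 2 samples of wild type on another array type were not analysed here.

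Per the file headers, the scanner files hold intensity values from Agilent Feature Extraction 10.5.1.1 for the 14 ChIP over input arrays and 9.5.1.1 or 9.5.3.1 for the 6 direct arrays, whose processed signals were background-subtracted, detrended and scaled by linear dye normalization within the array. The submitters' notes name version 9.1 for 4 of the older samples, and the headers were followed. Per the file headers, the raw columns are intensity without normalization and the scanner's own log ratio is log10 of red over green. The authors' probe tables hold a normalized log2 ratio, made by scaling both channels so that their medians agree, with ChIP Analytics 1.3 where the table is named after it. The table headings call the red channel the immunoprecipitate in every file, although tests on the values showed that the normalized ratio of the arrays over input ran ChIP (green) over input (red), as the labels state. The deposited series matrix holds log10 ratios, red over green, for 4 older samples and log2 ratios for the other 9, with the 2 arrays of a sample combined where there were 2. This was found by matching the values, which were equal within 0.001. Per the file headers, probe coordinates of the ChIP over input arrays are those of the sacCer1 build; for the direct arrays the build is not given in the sources used here, and probes were joined by their feature number.

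The log2 ratio of each probe was computed from the processed signals as ChIP over input, or as treated over control for the direct arrays. Features marked as outliers were left out, and each array was centred on its median. A coding value was the mean of the probes inside a gene and a promoter value the mean of promoter probes within 500 bp upstream of the start codon, with 3 or more probes each; control probes and mitochondrial genes were left out. A promoter probe within 500 bp of both neighbouring genes counted for both. As 2720 promoters were classed divergent and 2769 tandem, promoter counts and list tests hold values that share probes. In all, 172764 coding and 38665 promoter probes were used, with a median of 26 and 9 per gene. Genes with a near copy elsewhere were marked by probes that share a run of bases. Gene names were matched to a reference table for 5644 of 5665 identifiers. Arrays were read and tested in R 4.3.3 with limma 3.58.1 and the package data.table (version 1.17.8), and figures drawn in Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.

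The 8 Pol II arrays and the 6 Top2 arrays were each fitted together in limma with a mean per strain, which left 4 and 3 residual degrees of freedom. Changes were called at a Benjamini-Hochberg adjusted p under 0.05, two-sided, for each mutant against wild type and for the interaction in Pol II. The moderated variance of Pol II took a prior with 6.03 degrees of freedom, while for Top2 the prior was infinite and every gene had the same SE. On simulated data with changes added to 200 genes, a change of 1 on the log2 scale was found for 90% to 100% of genes and a change of 0.5 for 15% (interaction) to 79%. Gene lists were fixed before the data were examined, as were the comparisons, the tests and the rule for naming genes. The lists held ribosomal protein, glycolysis, heat shock and chaperone, general stress, ribosome biogenesis, galactose, phosphate, histone, meiosis, mating type, auxotrophy loci, mitochondrial ribosome, cell wall, oxidative phosphorylation (respiratory), subtelomeric, long (3 kb or more) and short (under 0.6 kb) genes. Lists of tRNA and of snoRNA genes had 0 members on the arrays' gene annotation and gave no result. The lists were tested with camera at a preset correlation of 0.01 and at an estimated correlation and with fry, adjusted over the lists of a comparison. Named genes were the 5 largest rises and the 5 largest falls among called genes with 5 or more probes and every mutant array on the same side of every wild-type array, up to 4 members of a list with the largest change, and 10 genes chosen in advance; on single arrays they were the 5 highest and 5 lowest. On the direct arrays the median of a list was placed among 10000 random lists of the same size matched on intensity in 10 bins, as a percentile.

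The files hold 8 scan days, named here by letters. Wild type and double mutant share days E and F, with 1 array of each antibody and strain per day, so the day was also fitted as a block, which pairs them. The arrays of top1 and of top2-ts were each scanned on a day of their own. For these the block has a term for days E and F only, and the day was also fitted as a random effect. Other settings were normexp background with an offset of 50, loess within arrays, equal spread of all arrays, quantile scaling, probes well above background, the median over probes, 8 or more probes, a variance trend with robust moderation, the authors' log2 ratios, the series matrix values, all 14 arrays in a single fit, promoters exchanged with coding regions, 250 bp promoters, and each array left out in turn. Added after the data were seen were fits with mitochondrial genes, without moderation, without the genes missing from an input, without chromosome VIII, and with all probes within 500 bp upstream. From 96.6% to 99.9% of features were well above background in the green channel, and the number of arrays limits the precision.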

Results

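Binding of Topoisomerase II (Top2), RNA polymerase II (Pol II) and histone H3 to budding yeast chromatin was measured by chromatin immunoprecipitation (ChIP) on dual-channel Agilent tiling arrays. Each array held 243504 features, of which 237908 were probes other than controls. Pol II over input was measured in wild type, in a top1 deletion strain, in a strain with a temperature-sensitive top2 allele (top2-ts) and in the double mutant (top1,top2-ts), with 2 arrays per strain after 1 h at 37 C. Top2 over input was measured in wild type, top1 and the double mutant, again with 2 arrays each. A further 6 samples were single arrays that compared a pair of ChIPs directly: H3 and Top2 after histone H4 depletion, Pol II and Top2 in the rpb1-1 Pol II mutant, and H3 and Top2 in the double mutant against wild type. Altogether 20 arrays from 13 of the 15 samples were used, and 2 samples hybridised to another array type were not analysed here. The median processed signal per array ran from 991.8 to 1309.8 in the green channel and from 970.2 to 1327 in the red channel, and the number of arrays limits the precision. Replicate arrays correlated across probes with r from 0.866 to 0.947 for Pol II, and with r of 0.952, 0.933 and 0.729 for Top2 in wild type, top1 and the double mutant; probes are not independent replicates. The labels do not say that the 2 arrays of a strain came from separate cultures, so every p-value measures only the spread between arrays.

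The identity of the strains was checked first. TOP1, the gene for Topoisomerase I, was depleted from the input of both strains labelled as deletions. The mean input signal over its coding region was lower than in wild type by a log2 difference of -3.23 ± 0.06 in top1 and -3.13 ± 0.21 in the double mutant on the Pol II arrays (± SD, n = 2). On the Top2 arrays the same differences were -3.00 and -3.01, and in top2-ts the difference was -0.10. TOP2, whose mutant allele keeps its DNA, differed by 0.04, 0.03 and -0.03 on the Pol II arrays. The direction of each Pol II ratio was checked on gene groups of known activity. The median log2 ratio of ribosomal protein genes lay between 1.07 and 2.42 on the 8 arrays, and that of meiotic genes, which are silent in dividing cells, between -0.93 and -0.53. The input also showed that a few genes were missing from some strains. PDR18, AIF1, YNR071C, YGL262W and COS12 had almost no input signal in wild type and top1, as did the promoters of HXT17 and MAN2. The promoter of HXT7 had almost none in the strains that carry top2-ts. The ratios of these genes compare background with signal, so their changes, marked where given below, do not measure binding. The strains that carry top2-ts thus differ from wild type at loci beside TOP1 and TOP2. Where top2-ts or the double mutant is compared with wild type, such strain differences cannot be told apart from the top2-ts allele.

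Where Top2 and Pol II sit in wild-type cells was asked next. Top2 was higher upstream of genes than over them. The log2 ratio at the promoter, within 500 bp of the start codon, exceeded that over the coding region by a median of 0.40 ± 0.13 (± SD, n = 2 arrays). It was the higher of both at 84.7% of genes. Divergent promoters, shared by genes on either side, exceeded their coding regions by 0.41, and tandem promoters by 0.39. Pol II showed the reverse, with a promoter minus coding difference of -0.26 ± 0.10. The promoters of glycolytic genes carried much Top2, with a median log2 ratio of 1.28, against 0.55 for ribosomal protein genes, 0.65 for heat-shock genes and 0.02 for meiotic genes. Top2 at the promoter increased with the Pol II level of the gene, from a median of 0.30 in the lowest of 5 equal groups of 1079 genes through 0.36, 0.42 and 0.54 to 0.71 in the highest. Across 5395 genes the correlation was weak (r = 0.268, rho = 0.272), and genes are not independent replicates.

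**Figure D1:**
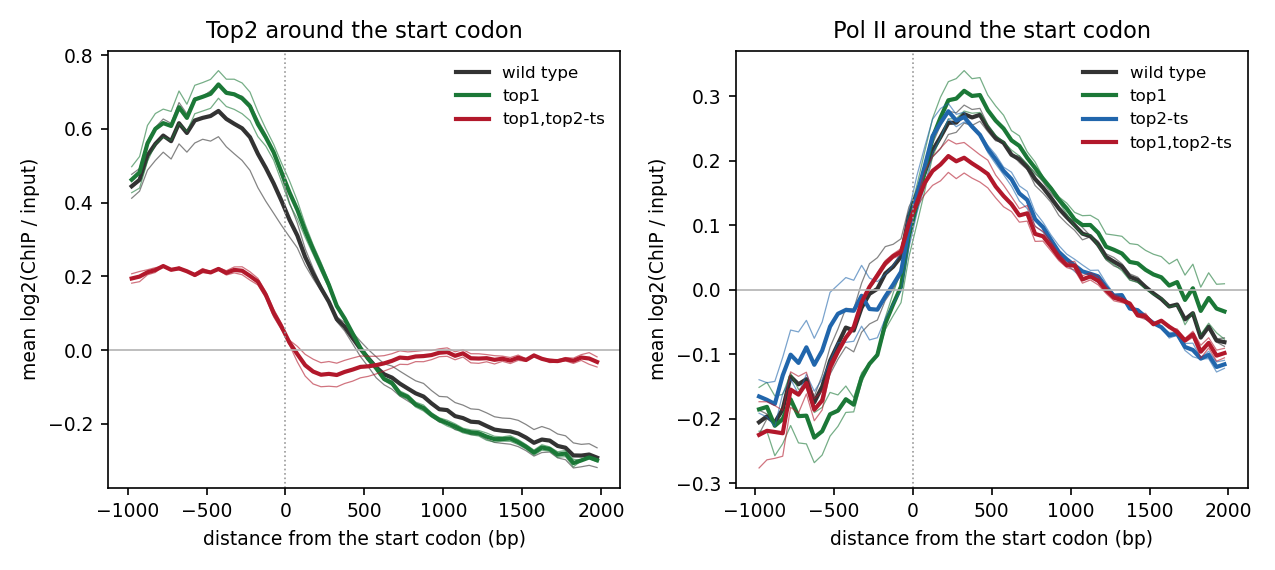
Mean log2 ratio of ChIP over input in bins of 50 bp around the start codon for Top2 (left) and Pol II (right), with thick lines for strains and thin lines for single arrays (2 per strain). Top2 peaks upstream of the start codon in wild type and top1 and is lower there in the double mutant, while Pol II peaks inside the genes.

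The comparison of the double mutant with wild type asked what the joint loss of both topoisomerases does to Pol II on genes. Pol II fell over 119 of the 129 measured ribosomal protein genes and rose over 0. The median level of the list was 2.12 ± 0.28 in wild type and 1.08 ± 0.009 in the double mutant (log2 ChIP over input, ± SD, n = 2 arrays). Glycolytic genes followed, with 15 of 19 lower and 0 higher, and a level of 2.40 ± 0.03 against 1.47 ± 0.10. Part of the heat-shock and chaperone genes went the other way, with 11 of 26 higher, 2 lower and 13 that did not pass, and a level of 0.73 ± 0.12 against 1.31 ± 0.05. Of 5494 genes tested, Pol II rose over 326 and fell over 817 in limma at an adjusted p under 0.05. Each array was centred on its median, so rises and falls are relative to the median probe. A change shared by the whole genome does not show, here and in every other comparison of arrays over input.

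The largest rise was over BTN2, a stress-induced gene for the sorting of misfolded proteins, on chromosome VII with its start codon at position 772456 of the sacCer1 build named in the file headers. Its log2 ratio went from -0.26 ± 0.27 to 1.73 ± 0.12 (± SD, n = 2), a change of 1.99 ± 0.17 (± SE, adjusted p = 0.000239) or 3.96-fold. Next came CHA1, for an enzyme that breaks down serine and threonine (1.28 ± 0.21, adjusted p = 0.00262), RTR1, for a phosphatase that acts on Pol II (1.05 ± 0.16), ATG3, an autophagy gene (1.01 ± 0.14), and PES4 (0.94 ± 0.25, adjusted p = 0.0243). The largest fall was over ILV5, for an enzyme of branched-chain amino acid synthesis, on chromosome XII with its start codon at position 839252. Its ratio went from 3.29 ± 0.16 to 1.12 ± 0.08 (change -2.17 ± 0.12, adjusted p = 3.03e-05). The double mutant also had more input signal at the auxotrophy locus LEU2, by 0.88. The fall over ILV5 cannot be told apart from this difference in LEU2 DNA. Pol II also fell over the ribosomal genes RPP0 (-2.07 ± 0.14, adjusted p = 8.48e-05) and RPL38 (-1.92 ± 0.14), over ASC1, for a ribosome-bound signalling protein (-1.92 ± 0.15), and over YGL262W (-2.00 ± 0.46), which is missing from the wild-type input. Among the genes named in advance, the histone genes HHT1 (-0.91 ± 0.13, adjusted p = 0.00168) and HHT2 (-0.94 ± 0.14) fell, as did RPO21, for the largest Pol II subunit (-0.63 ± 0.12, adjusted p = 0.00648). TOP2 (0.32 ± 0.10, adjusted p = 0.0549), PHO5 (-0.34 ± 0.12, adjusted p = 0.0659), GAL1 (0.10, adjusted p = 0.631), GAL10 (-0.07, adjusted p = 0.738) and the deleted TOP1 (-0.07, adjusted p = 0.718) did not pass the test.

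By gene list, the median change over ribosomal protein genes was -1.07, with RPL31B at -1.77 ± 0.15 and RPS17A at -1.57 ± 0.13, and 128 of them fell when adjusted over the list alone. Over glycolytic genes the median change was -0.58, with PDC1 (-1.75 ± 0.15), PGK1 (-1.61 ± 0.16), CDC19 (-1.14 ± 0.15) and TPI1 (-1.04 ± 0.14) the furthest down, and 16 fell when adjusted over the list alone. The heat-shock median was 0.41, with HSP30 (0.90 ± 0.11), CPR6 (0.89 ± 0.19) and HSP26 (0.88 ± 0.16) after BTN2, and 14 rose and 2 fell when adjusted over the list alone. Histone genes had a median of -0.72 with 7 of 9 lower (8 adjusted over the list alone), led by HTB2 (-1.17 ± 0.19) and HTA2 (-0.98). Cell wall genes had a median of -0.49 with 10 of 24 lower (14 adjusted over the list alone), among them FKS1, for a glucan synthase (-1.25 ± 0.11), and CCW12 (-1.20 ± 0.21). Phosphate-response genes had a median of -0.34 with 6 of 13 lower (8 adjusted over the list alone), led by the transporter gene PHO84 (-0.96 ± 0.16). Meiotic genes, with almost no Pol II in wild type, had a median of 0.29 with 9 of 30 higher and 2 lower (14 and 2 adjusted over the list alone).

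All 7 medians kept their direction under other scalings but not their size. Under quantile scaling they were -0.68 for ribosomal protein, -0.25 for glycolytic, 0.73 for heat-shock, -0.31 for histone, -0.10 for cell wall, -0.21 for phosphate-response and 0.19 for meiotic genes. Under equal spread they were -0.38 for glycolytic, -0.44 for histone, -0.26 for cell wall and 0.16 for meiotic genes. These 7 lists differed from the other genes in camera with its preset correlation of 0.01, with adjusted p = 3.52e-48 for ribosomal protein, 6.72e-08 for glycolytic, 4.36e-06 for heat-shock, 0.000564 for both histone and cell wall, 0.00141 for meiotic and 0.0166 for phosphate-response genes. None of the camera calls of any comparison held with an estimated correlation; here all 7 had an adjusted p = 0.453 with an estimated correlation. The fry test, whose first p-value asks whether the genes of a list move on balance in a single direction and whose mixed p-value asks whether they change in either direction, compares no list with other genes. Its first adjusted p was 0.0186 for ribosomal protein and phosphate-response, 0.031 for glycolytic, histone and cell wall, 0.0615 for heat-shock and 0.0833 for meiotic genes. The mixed adjusted p of these 7 lists ran from 0.000453 to 0.00534, but it passed for every other list too except galactose genes (0.138), down to 9.73e-05 for subtelomeric genes. The auxotrophy loci had a fry adjusted p of 0.025. The remaining lists had a camera adjusted p from 0.133 to 0.904. General stress genes had a median of -0.02 (1 higher, 2 lower), which became 0.004 after loess and up to 0.04 under quantile scaling. Ribosome biogenesis genes had a median of -0.09 (0 higher, 8 lower, 7 adjusted over the list alone), which became 0.05 under equal spread and 0.13 under quantile scaling. Respiratory genes had a median of -0.20 (10 of 33 lower, 11 adjusted over the list alone) and mitochondrial ribosome genes of 0.09 (5 higher, 5 lower, 2 and 4 adjusted over the list alone). Mating-type genes had a median of 0.18 (1 higher, 1 lower, the same numbers adjusted over the list alone). Galactose genes had a median of 0.04 (1 higher, GAL7 at 0.60 ± 0.18, and 0 adjusted over the list alone), turning to -0.05 under equal spread. Auxotrophy loci had a median of -0.02 and a mean of -0.25 (2 of 9 lower, 3 adjusted over the list alone), with a median of 0.15 under quantile scaling. The lowest ratio change was at LEU2 (-0.91 ± 0.11), whose input signal was higher in the mutant by 0.88 while its ChIP signal differed by 0.02. Subtelomeric genes had a median of 0.002 (11 higher, 13 lower, the same adjusted over the list alone), turning to -0.06 under equal spread; 9 were lower without the genes missing from an input.

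**Figure D2:**
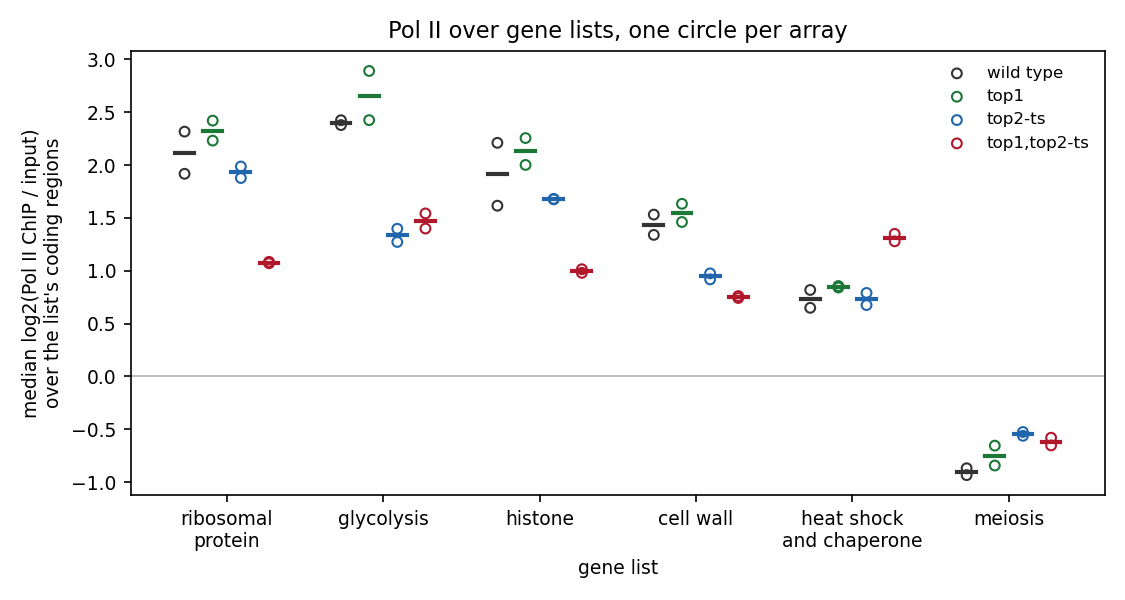
Median log2 ratio of Pol II ChIP over input across the coding regions of 6 gene lists, with a circle per array and a bar at the mean of the 2 arrays of each strain. In the double mutant the ribosomal protein list sits at 1.08 against 2.12 in wild type, and the heat-shock list at 1.31 against 0.73.

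The change in the double mutant followed the wild-type Pol II level. With genes ranked on the wild-type array that was not used for the change, the median change of the 5 equal groups was 0.13, 0.05, 0, -0.10 and -0.35 from the lowest to the highest level. The last group differed from the first by -0.48, or by -0.25 when all arrays were given equal spread. By coding length, the median change was -0.01 over 831 genes under 0.6 kb and 0.03 over 463 genes of 3 kb or more. This gap of 0.04 turned to -0.05 under equal spread, to -0.006 without double mutant replicate 1 and to -0.07 without wild-type replicate 1. Long genes had less Pol II in wild type than short ones (a median of -0.21 against 0.39). In a split by level and length that was not planned, long genes lay below short genes in each of the 5 level groups: 0.11 against 0.17, 0.02 against 0.06, -0.10 against 0.03, -0.17 against -0.04, and -0.50 against -0.30. The SD between both choices of the ranking array was up to 0.23 for short genes, and the highest group held 22 long genes. Among short genes 39 rose and 122 fell (36 and 120 adjusted over the list alone), TSA1 at -1.51 among them, and their median turned to 0.06 under quantile scaling. Among long genes 37 rose and 45 fell (35 and 44 adjusted over the list alone), with YEF3, for a translation elongation factor, at -1.09. Wild type and double mutant were scanned together on both of a pair of days, called E and F. The per-gene changes of both days correlated with r = 0.706 (rho = 0.647) over all genes. With the scan day as a block 236 genes rose and 714 fell. The ribosomal protein median was -1.24 on day E and -0.86 on day F, and the heat-shock median 0.52 and 0.21. Of the genes called, 71.5% were lower, which became 61.8% under equal spread (507 higher, 820 lower) and 696 higher against 771 lower under quantile scaling. Leaving out double mutant replicate 1 or 2 left 322 or 417 genes.

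**Figure D3:**
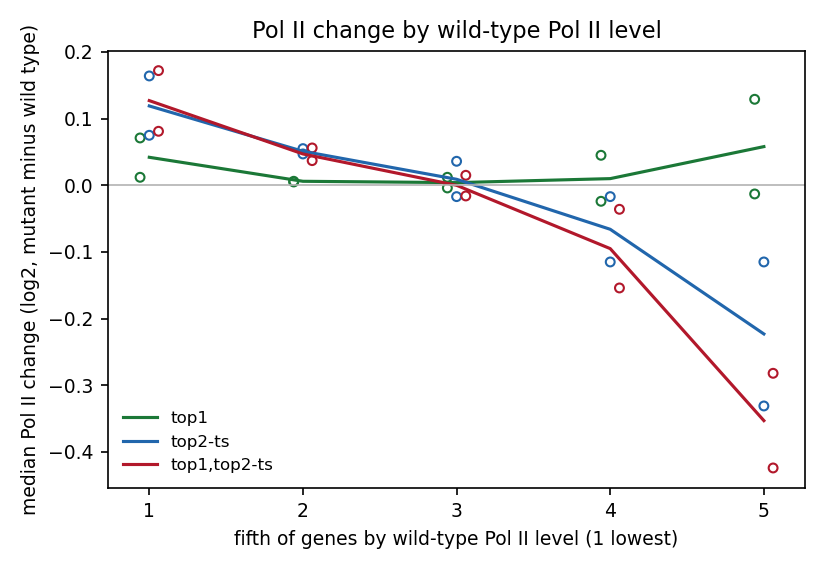
Median log2 change of Pol II, mutant minus wild type, in 5 equal groups of genes ranked by wild-type Pol II level, with a circle for each choice of the ranking array and lines at their mean. In the double mutant the line runs from 0.13 in the lowest group to -0.35 in the highest, and in top1 it stays between 0.004 and 0.06.

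The top1 strain asked what loss of Topoisomerase I alone does to Pol II. Only 7 genes rose and 3 fell of 5494 tested in limma (459 at an unadjusted p under 0.05). Pol II rose over TRP1 (1.09 ± 0.13, adjusted p = 0.00743) and URA3 (1.09 ± 0.15, adjusted p = 0.015), genes of tryptophan and uracil synthesis that serve as selection markers. In the double mutant, which also lacks TOP1, their ChIP signals differed from wild type by 0.009 and 0.25. These rises therefore cannot be assigned to the loss of Topoisomerase I rather than to other strain differences. Pol II fell over LEU1 (-1.14 ± 0.12, adjusted p = 0.00363), which acts in leucine synthesis, and over the transporter gene OAC1 (-0.81 ± 0.12, adjusted p = 0.0234). The ratio of LEU2 was lower too (-0.91 ± 0.11, adjusted p = 0.00798), but its input signal was higher in top1 by 1.00 while its ChIP signal differed by 0.09 ± 0.11 (± SD, n = 2), so this is not a loss of Pol II signal. The falls over LEU1 and OAC1 in top1 cannot be told apart from this difference in LEU2 DNA. Their ChIP signal was also lower in top2-ts, by -0.64 and -0.53, where the LEU2 input differed by 0.07. The deleted TOP1 had a ratio 0.95 ± 0.13 higher (adjusted p = 0.0132), where the input was lower by -3.23 than in wild type but 89.6% of the probes were still well above background. This value turned to -0.23 with normexp background. The other calls were PUT1, for an enzyme of proline use, named here after its value was seen (0.81 ± 0.11, adjusted p = 0.0132), and PDR18 (2.13), AIF1 (2.12) and YNR071C (1.99), all 3 missing from the input of both strains. In all, 6 genes were called once the genes missing from an input were left out. HHT1 (0.46, adjusted p = 0.447), HHT2 (0.36), PHO5 (0.17), GAL1 (0.11), RPO21 (0.10), TOP2 (0.07) and GAL10 (0.04) did not pass the test.

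Several gene lists lay slightly above the other genes in top1, although outside the auxotrophy loci and the genes above no member passed on its own. The median change was 0.23 over ribosomal protein genes (camera adjusted p = 2.86e-15), 0.21 over ribosome biogenesis genes (7.63e-09), 0.25 over glycolytic genes (0.000165), and 0.17 over phosphate-response genes (1.41e-05). It was 0.23 over histone genes (0.00777), 0.16 over heat-shock genes (0.00311), 0.10 over meiotic genes (0.04) and 0.07 over respiratory genes (0.0474). With an estimated correlation the adjusted p of phosphate-response genes was 0.437 and that of the other 7 lists 0.543, and the first fry p passed for no list (the lowest adjusted p was 0.0746). The mixed fry p passed for phosphate-response genes (adjusted p = 0.000272), auxotrophy loci (0.000299), subtelomeric genes (1.38e-05) and long genes (0.0338), and for no other list. Without the genes missing from an input, a fit added after the data were seen, it was 0.0774 for both subtelomeric and long genes, and 0.000448 for the other 2 lists. Of the phosphate-response genes, 4 rose when adjusted over the list alone and 0 over all genes, with PHO84 at 0.84 ± 0.16 and SPL2 at 0.72 ± 0.13. Under quantile scaling the ribosomal protein median was 0.025, the histone median 0.10 and the respiratory median 0.04 (0.13 with normexp background), and the glycolytic median turned to -0.04. Without wild-type replicate 1 the heat-shock median became -0.005, while without top1 replicate 2 the meiotic median was 0.02 with its test on the opposite side. Long genes had a median of 0.08 (camera adjusted p = 2.44e-05, 1 higher, which is PDR18, missing from the input) and short genes of -0.03 (0.0196, 0 called), the latter turning to 0.06 without wild-type replicate 1; with an estimated correlation these had an adjusted p of 0.543 and 0.657. Within groups of like wild-type level, long genes again lay above short ones, by 0.10 against -0.06 in the lowest group and 0.15 against 0.04 in the highest, where the SD between ranking arrays was 0.165 for short genes. The 5 groups by wild-type level changed by 0.04, 0.006, 0.004, 0.01 and 0.06. The other lists gave no camera call: subtelomeric genes had a median of 0.06 (3 higher, 4 adjusted over the list alone, and 0 of either in limma without the genes missing from an input) and auxotrophy loci of 0.22 (2 higher and 1 lower, 3 and 1 adjusted over the list alone). The median was 0.08 for cell wall genes (-0.02 under quantile scaling), -0.08 for general stress, 0.04 for galactose, 0.02 for mating-type and 0.01 for mitochondrial ribosome genes. The top1 arrays were scanned on a day of their own, so the strain and the day could not be separated. Leaving out top1 replicate 2 left 3 genes, and with promoters in place of coding regions 1 gene was called.

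The top2-ts strain asked the same for Topoisomerase II alone. Pol II fell over genes of the glycolytic pathway (11 of 19 lower, 0 higher), from a level of 2.40 ± 0.03 in wild type to 1.33 ± 0.09 in top2-ts (± SD, n = 2 arrays). Of 24 cell wall genes 11 were lower, 0 higher and 13 did not pass, and of 30 meiotic genes 6 were higher, 0 lower and 24 did not pass. Of 5494 genes, 101 rose and 288 fell in limma. The largest falls were over TMN2 (-1.53 ± 0.13, adjusted p = 0.00146), over HPF1, for a cell wall mannoprotein (-1.32 ± 0.17), and over CSS1 (-1.27 ± 0.17), beside YGL262W and COS12, which are missing from the wild-type input. The largest rises were over HSK3, for a kinetochore protein (0.88 ± 0.20, adjusted p = 0.0336), and the end-joining gene NEJ1 (0.82 ± 0.13). The vitamin B6 gene SNZ1 (0.78 ± 0.13), FIG1, which acts in mating (0.78 ± 0.17), and the meiotic gene RED1 (0.77 ± 0.20) followed.

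Among glycolytic genes the median change was -0.62 (-0.41 under quantile scaling), with PDC1 (-1.21 ± 0.15), CDC19 (-1.15), ENO2 (-1.02) and ADH1 (-0.97) the lowest (17 fell when adjusted over the list alone, camera adjusted p = 3.05e-11). Cell wall genes had a median of -0.52, with CCW12 (-1.10), HSP150 (-0.90) and CWP2 (-0.84) the lowest (18 fell when adjusted over the list alone, 1.29e-10). Meiotic genes had a median of 0.35, with SPS4 (0.66) and REC8 (0.65) among the highest (17 rose when adjusted over the list alone, 3.9e-10). Phosphate-response genes had a median of -0.35, with SPL2 (-0.999) and PHO84 (-0.92) (3 of 13 fell, 7 adjusted over the list alone, 0.000303). The adjusted p with an estimated correlation was 0.351 for glycolytic genes and 0.255 for the other 3 lists; their first fry adjusted p was 0.0364 and 0.0222, and their mixed one from 0.00134 to 0.0096. Auxotrophy loci had 0.0222 and 0.00202. Mixed values also passed for respiratory, subtelomeric and long (0.000864 each), short and mitochondrial ribosome (0.00305 each) and mating-type genes (0.0072). Ribosomal protein genes had a median of -0.20, which turned to 0.18 under quantile scaling and 0.04 under equal spread. Pol II fell over 16 of 129 (22 adjusted over the list alone, camera adjusted p = 5.39e-06, adjusted p = 0.897 with an estimated correlation), RPL2A (-1.07 ± 0.18) and RPL10 (-0.89) among them. General stress genes had a median of -0.22 with 1 lower (1 adjusted over the list alone, 0.00608, adjusted p = 0.786 with an estimated correlation). The remaining lists had a camera adjusted p from 0.0797 to 0.902. Histone genes had a median of -0.20 (1 of 9 lower, 1 adjusted over the list alone), turning to 0.08 under quantile scaling and 0.009 under equal spread, with HHT1 at -0.55 ± 0.13 (adjusted p = 0.0413). Auxotrophy loci had a median of -0.19 with 2 of 9 lower (2 adjusted over the list alone), LEU2 and HIS3, the latter with 0.59 more input and a ChIP difference of -0.16. Heat-shock genes had a median of -0.08 (1 lower, 0 adjusted over the list alone) and mitochondrial ribosome genes of 0.06 (1 higher, 2 lower, the same adjusted over the list alone). Ribosome biogenesis genes had a median of -0.04, turning to 0.06 under quantile scaling (0 called). Respiratory genes had a median of -0.07, turning to 0.03 under quantile scaling (2 lower, 6 adjusted over the list alone). Subtelomeric genes had a median of -0.02 (5 higher, 10 lower, 7 and 14 adjusted over the list alone), with 6 lower without the genes missing from an input. Long genes had a median of -0.02 (5 higher, 19 lower, 2 and 14 adjusted over the list alone) and short genes of -0.001, turning to 0.09 under quantile scaling (18 higher, 34 lower, 16 and 27 adjusted over the list alone). Galactose genes had a median of -0.006, turning to 0.06 with normexp background (0 called). Mating-type genes had a median of -0.09 with a mean of 0.01, turning to 0.14 under quantile scaling (1 lower, 1 adjusted over the list alone). HHT2 (-0.39, adjusted p = 0.109), RPO21 (-0.35, adjusted p = 0.104) and PHO5 (-0.34, adjusted p = 0.101) did not pass the test. By wild-type level the 5 groups changed by 0.12, 0.05, 0.009, -0.07 and -0.22. Within each of these groups long genes lay below short ones, at 0.06 against 0.16 in the lowest and -0.30 against -0.17 in the highest, where the SD between ranking arrays was 0.25 for short genes and 22 genes were long.

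The calls in top2-ts were less certain than those in the double mutant. Its arrays were scanned on a day of their own, and leaving out top2-ts replicate 1 or 2 left 2 or 1 genes, against 105 without wild-type replicate 2. Of the called genes 74% were lower, which fell to 213 higher against 220 lower under quantile scaling and 140 higher against 242 lower under equal spread.

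Whether the double mutant changed by more than both single mutants together was tested with the interaction: the change in the double mutant minus the sum of the changes in top1 and top2-ts. Ribosomal protein genes were far below that sum, with a median difference of -1.06 and 91 of 129 genes lower and 0 higher. Glycolytic genes, with a median of -0.24 that turned to 0.15 under quantile scaling, had 4 of 19 lower and 0 higher (4 and 0 adjusted over the list alone). The list level of ribosomal protein genes was 2.33 ± 0.13 in top1 and 1.93 ± 0.08 in top2-ts, against 2.12 ± 0.28 in wild type and 1.08 ± 0.009 in the double mutant. RPL38 (-2.43 ± 0.19, adjusted p = 0.000953), RPL26A (-2.13 ± 0.24) and RPL31B (-1.94 ± 0.22) were the furthest below the sum, beside PDR18 and YNR071C, which are missing from an input. BTN2 was the furthest above it (1.56 ± 0.24, adjusted p = 0.0123), followed by YHR007C-A (1.33 ± 0.21), AGA1, for a mating agglutinin (1.24 ± 0.20), FUN19 (1.18 ± 0.17) and HPF1 (1.17 ± 0.24). In all, 76 genes were above and 247 below the sum, and 74 and 229 without the genes missing from an input. The top1 and top2-ts arrays were each scanned on a day of their own, so the interaction cannot be told apart from the scan day. With a block for days E and F, which has no term for these days, 38 genes were above and 152 below.

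Heat-shock genes were above the sum by a median of 0.35, or 0.64 under quantile scaling (2 higher, 7 higher and 1 lower adjusted over the list alone, camera adjusted p = 0.00021). General stress genes were above it by 0.34 (1 higher, 4 adjusted over the list alone, 0.000532). Below it were ribosomal protein genes (121 adjusted over the list alone, 6.56e-50), and histone genes by a median of -0.82, or -0.49 under quantile scaling (3 of 9 lower, 6 adjusted over the list alone, 0.000532), with HHT1 at -0.82 ± 0.19 and HHT2 at -0.91. So were ribosome biogenesis genes by -0.26 (6 of 43 lower, 8 adjusted over the list alone, 0.00328) and meiotic genes by -0.20 (3 of 30 lower, 3 adjusted over the list alone, 0.0259). With an estimated correlation the adjusted p of these lists was 0.78, 0.843 for ribosome biogenesis and 0.841 for meiotic genes, and the first fry p passed for no list (the lowest adjusted p was 0.137). The mixed fry p passed for all 6 lists, from an adjusted p of 0.002 for meiotic to 0.0485 for general stress genes, with 0.00793 for ribosomal protein genes. It also passed for every other list except glycolytic, galactose and mating-type genes, down to 0.000522 for subtelomeric genes. The other lists had a camera adjusted p from 0.0758 to 0.903. The deleted TOP1 had an interaction of -0.80, which includes this ratio of dim signals in top1. Leaving out either double mutant array left 23 or 8 genes, leaving out top2-ts replicate 1 or 2 left 82 or 34, and leaving out top1 replicate 1 left 27. Under quantile scaling 253 genes were above and 421 below.

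Because all 3 mutants were compared with the same 2 wild-type arrays, their changes share noise. The changes in the double mutant and top2-ts correlated with r = 0.521 across genes, where shared noise alone gave 0.5 in 100 simulations, but their covariance was 0.0562 against 0.00965 simulated. Of the called genes, 192 fell in both, where 42.8 would do so if the calls were independent, and 24 rose in both, against 6. The 2 wild-type arrays were not divided between both comparisons, so part of the overlap may come from them. Other differences from wild type that both strains share, as seen in the input, may add to the overlap too. The changes in top1 and the double mutant correlated with r = 0.011, and those in top1 and top2-ts with r = 0.109, both below the 0.5 and 0.501 that shared noise alone gave. Their covariances were 0.000802 and 0.00587, against 0.00965 and 0.00967 simulated.

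Top2 ChIP in the double mutant against wild type asked where Top2 binding changes when the temperature-sensitive protein is inactivated in the absence of Topoisomerase I. Values are relative to the median probe, so a loss of Top2 shared by the whole genome would not show. Top2 fell at 3004 of 5489 promoters and rose at 378 in limma, and the promoter minus coding difference went from 0.40 ± 0.13 in wild type to 0.14 ± 0.05 (± SD, n = 2 arrays). The double mutant arrays were flatter over all probes, with a median absolute deviation of 0.30 and 0.34 against 0.60 and 0.50 in wild type. The median promoter changed by -0.34, or by -0.46 with normexp background and -0.23 under quantile scaling, so list changes are given relative to the median promoter of the same scaling. Relative to it, Top2 was lower at general stress genes by -0.54 (from -0.62 to -0.44 over all scalings), at glycolytic genes by -0.35 (from -0.40 to -0.08), and at histone genes by -0.32 (from -0.38 to -0.06). Phosphate-response genes lay lower by -0.30 (from -0.45 to -0.29). It was higher at heat-shock genes by 0.52 (from 0.47 to 1.00), at meiotic genes by 0.51 (from 0.40 to 0.56) and at ribosomal protein genes by 0.15 (from 0.12 to 0.32). The lists that lay lower had wild-type Top2 levels from 0.97 to 1.28, against 0.65, 0.02 and 0.55 for those that lay higher. Under equal spread the change was -0.54 for general stress, -0.38 for phosphate-response and -0.09 for glycolytic and histone genes. Promoters were not matched on wild-type Top2 level, so a flattening of all strong promoters was not told apart from changes of single lists.

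The largest fall in Top2 was at NVJ1, for a protein of the junction between nucleus and vacuole (-2.45, relative change -2.11, adjusted p = 2.4e-69), followed by AFR1, TMA10, CSR1 and YHR086W-A, with relative changes from -1.68 to -1.54. Every gene had the same SE of 0.14, because limma found no spread between genes beyond sampling and gave all a single variance. P-values this small rest on that single variance and do not measure shifts of whole arrays. The median promoter changed by -0.42 on day E and -0.28 on day F. Without moderation limma called 1830 promoters. The trehalose genes TPS1, TSL1 and TPS2, of the general stress list, had relative changes of -1.46, -1.23 and -1.04, and the glycolytic genes PGK1 and ENO1 of -1.09 and -0.99. The largest rise was at RRP6, for an exonuclease of the RNA exosome (1.302, relative change 1.65, adjusted p = 2.1e-20), followed by INP1, FES1, VPS3 and PRP45, with relative changes from 1.33 to 1.27. The histone genes HHT2 (-1.06), HHF2 (-0.95), HHT1 (-0.84) and HHF1 (-0.73) fell, as did TOP1 (-0.44, adjusted p = 0.00272, relative change -0.09) and PHO5 (-0.37, adjusted p = 0.0111, relative change -0.03). RPO21 (0.34, adjusted p = 0.0222) and TOP2 (0.31, adjusted p = 0.0341) rose, while GAL1 (0.19, relative change 0.53) and GAL10 (0.08, relative change 0.42) did not pass the test.

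Over all promoters Top2 fell at 3004 of 5489 and rose at 378, so a list with a like share of falls is not set apart. The shares of galactose, mating-type, mitochondrial ribosome, subtelomeric and long genes given below lie near or below it. In counts, Top2 fell at 25 of 25 general stress promoters (25 adjusted over the list alone, camera adjusted p = 6.82e-07), 18 of 19 glycolytic (18, 0.00184) and 11 of 13 phosphate-response promoters (11, 0.015), each the same when adjusted over the list alone. It rose at 9 and fell at 5 of 26 heat-shock promoters (8 and 5 adjusted over the list alone, 0.000156). Likewise it rose at 10 and fell at 7 of 30 meiotic promoters (the same adjusted over the list alone, 0.000156). At ribosomal protein promoters it rose at 13 and fell at 57 of 136 (13 and 56 adjusted over the list alone), with a median of -0.19 that turned to 0.03 under quantile scaling and equal spread. Camera found this list to lose less Top2 than other promoters (adjusted p = 0.0226). With an estimated correlation every list had an adjusted p of 0.999. Without a camera call, Top2 fell at 10 of 11 histone promoters (10 adjusted over the list alone), 28 of 34 respiratory promoters (28), 6 of 11 galactose promoters (6) and 4 of 8 mating-type promoters (4), and rose at 0 of these. It rose at 2 and fell at 15 of 23 cell wall promoters (the same adjusted over the list alone), whose relative change of -0.24 turned to 0.16 under quantile scaling and 0.20 under equal spread. It rose at 4 and fell at 36 of 65 mitochondrial ribosome promoters (the same adjusted over the list alone). It rose at 4 and fell at 18 of 43 ribosome biogenesis promoters (4 and 17 adjusted over the list alone) and rose at 1 and fell at 1 of 9 auxotrophy loci (0 and 1 adjusted over the list alone). At subtelomeric promoters it rose at 9 and fell at 67 of 130 (9 and 66 adjusted over the list alone). Long genes had 40 higher and 224 lower (38 and 223 adjusted over the list alone) and short genes 41 higher and 526 lower (42 and 528 adjusted over the list alone). The changes of days E and F correlated with r = 0.905 (rho = 0.899) over all promoters. The median promoter changed by -0.42 on day E and -0.28 on day F, and with the day as a block 394 promoters rose and 3045 fell. Of the calls, 88.8% were lower, against 670 higher and 2438 lower under equal spread and 709 higher and 2381 lower under quantile scaling.

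Top2 in top1 against wild type asked whether loss of Topoisomerase I alone shifts Top2. Of 5489 promoters 50 rose and 6 fell in limma (836 at an unadjusted p under 0.05), with a median of 0.09 over all promoters. Top2 rose at the shared promoter of the histone genes HHT2 (0.71, adjusted p = 0.000144) and HHF2 (0.69, adjusted p = 0.000254), at the chaperone gene SSA1 (0.68, adjusted p = 0.000461) and at FES1, for a partner of that chaperone (0.58). It fell at EMP46 (-0.57, adjusted p = 0.00643), YHR086W-A (-0.55), HBT1 (-0.53), PFY1, for profilin (-0.51), and YNL195C (-0.50). The promoters of YNR071C, AIF1, HXT17 and MAN2 were missing from the input of both strains. By list, the counts were 2 of 26 heat-shock promoters higher (7 adjusted over the list alone), 2 of 11 histone promoters (2), which are the shared promoter of HHT2 and HHF2, 1 of 19 glycolytic promoters (5, with 1 lower), 1 of 13 phosphate-response promoters (4) and 1 of 65 mitochondrial ribosome promoters (1). Here and in the next sentence the numbers in brackets are adjusted over the list alone. Subtelomeric promoters had 6 of 130 higher (7), or 1 of 123 without those missing from an input, long genes 4 higher and 1 lower (8 and 1) and short genes 8 and 2 (8 and 2). None passed over all genes among ribosomal protein, general stress, ribosome biogenesis, galactose, mating-type, auxotrophy, cell wall and respiratory promoters, and the lists had medians from 0.04 to 0.21 apart from meiotic promoters. Normexp background turned the medians of general stress (-0.03), mating-type (-0.09), subtelomeric (-0.03), short (-0.02) and galactose genes (-0.002) below 0, and quantile scaling those of general stress (-0.003) and mating-type genes (-0.004). Meiotic promoters were below the others (camera adjusted p = 0.00396, adjusted p = 0.993 with an estimated correlation). They had a median of 0.01 that turned to -0.02 with normexp background, a mean of -0.04 and 0 called over all genes (1 lower adjusted over the list alone). The count rested on the scaling and on single arrays. With limma, 0 promoters were called with normexp background (375 at an unadjusted p under 0.05) or equal spread (369) and 1 under quantile scaling. The fit called 5 without wild-type replicate 2, 6 without top1 replicate 2 and 167 without wild-type replicate 1.

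The H4 depletion arrays asked whether Top2 moves to DNA that loses nucleosomes. They compared cells of a strain whose only H4 gene is driven by a galactose promoter after 6 h in glucose with the same strain in galactose, on a single array per antibody. The sugar changed together with H4, so H4 depletion cannot be told apart from the change of sugar at any gene. None of the 6 direct comparisons has a replicate check or a p. Each array was centred on its median, so a change shared by the whole genome does not show, and values are relative to the median probe. In these terms, promoters with lower H3 had higher Top2: from the lowest to the highest of 5 equal groups of promoters ranked by H3 change, the median Top2 change was 0.36, 0.20, 0.10, -0.02 and -0.19 (log2 depleted over control). Heat-shock promoters had a lower H3 (median -0.37, below all of 10000 random lists matched on intensity) and a higher Top2 (0.36, percentile 99.8). Galactose promoters, which glucose shuts off, had a higher H3 (0.91, percentile 100) and a Top2 change of -0.13 (percentile 3.85). H3 was the highest at GAL2 (3.32), SRD1 (2.61), GAL7 (2.59), GAL1 (2.48) and YBR013C (2.40), with GAL10 at 2.17. It was the lowest at AHP1, for a thioredoxin peroxidase (-2.04), YDL124W (-1.68), HSP12, for a small heat-shock protein (-1.64), TPO2 (-1.61) and YLR108C (-1.59).

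Top2 was the highest at CYM1 (1.73), NPL3, for an RNA-binding protein (1.73), YKR018C (1.64), COQ2 (1.41) and MVD1 (1.41), and the lowest at SRD1 (-2.14), YOL029C (-1.64), YCL001W-A (-1.55), RRP6 (-1.34) and RRG1 (-1.27). HSP12 had a Top2 change of 0.72, GAL1 of -0.13 and GAL7 of 0.63. Of the other lists, H3 was high at the promoters of ribosomal protein genes (0.50, percentile 100) and respiratory genes (0.50, percentile 100) and low at those of glycolytic (-0.26, percentile 0), general stress (-0.20, percentile 0.02) and subtelomeric genes (-0.06, percentile 0). Top2 was low at meiotic (-0.34, percentile 0) and histone promoters (-0.31, percentile 0.08), and at ribosomal protein promoters it was 0.12 (percentile 78.1). Among histone genes H3 was 1.40 at the promoter of HHF2, 0.76 at HHT2, -0.19 at HHF1 and -0.51 at HHT1. As the only H4 gene of this strain is driven by a galactose promoter, the H4 genes HHF1 and HHF2 may not be in their native state. Probes of galactose promoters may also read the construct. Neither was checked, as these arrays have no input. Across 5488 promoters H3 and Top2 changes correlated with r = -0.509 (rho = -0.521), and over coding regions with r = -0.536. The Top2 change was unrelated to the wild-type Top2 level (r = -0.006). Across probes the H3 array correlated with the Top2 array of this experiment with r = -0.595. It also correlated with the Top2 array of rpb1-1, an experiment without H4 depletion, with r = -0.407. Both Top2 arrays correlated with each other with r = 0.487. The relation of H3 and Top2 therefore cannot be assigned to H4 depletion alone, and the source of the shared part was not tested.

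**Figure D4:**
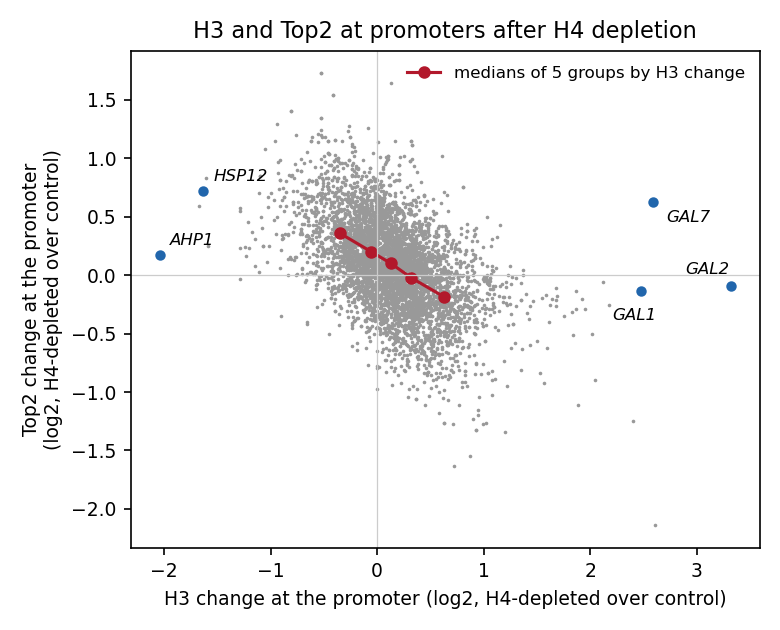
Log2 change of H3 (horizontal) and of Top2 (vertical) at each promoter after H4 depletion, depleted over control, 1 array each, with the median of 5 equal groups by H3 change in red. The medians run from 0.36 to -0.19, HSP12 lies at -1.64 for H3 and 0.72 for Top2, and GAL1 at 2.48 and -0.13.

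The rpb1-1 arrays asked whether Top2 binding follows transcription, by comparing a strain with the temperature-sensitive rpb1-1 subunit of Pol II with its RPB1 control after the temperature shift. Pol II was low over ribosomal protein genes (median -1.03, percentile 0), with RPS27B at -2.33 and RPL25 at -2.13, and over ribosome biogenesis genes (-0.76, percentile 0.01), with NSR1 at -1.99. It was high over heat-shock genes (1.40, percentile 100), with HSP42 at 3.60, BTN2 at 2.94, HSP26 at 2.21 and SIS1 at 2.11. It was also high over mating-type genes (1.06, percentile 100), with HMRA1 at 2.52 and STE2 at 1.89, and over general stress genes (0.48, percentile 99.96). The arrays compare separate strains, Z460 and Z579, without an input. Other differences between these strains, at mating-type genes among others, cannot be told apart from an effect of rpb1-1. The lowest genes were RIM1 (-4.65), LSM5 (-4.60), SHU1 (-4.32), which lies on chromosome VIII, where the whole chromosome was low, DUT1 (-3.61) and FMP23 (-3.57). Of all genes 886 were below -1 and 280 above 1, with a median of -0.12. Genes with more Pol II in wild type had a lower change relative to the median probe, from 0.12 in the lowest of 5 groups to -0.45 in the highest. Long genes had a median of 0.23 (percentile 100) and short genes of -0.48 (percentile 0).

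Both arrays were centred on their median, so a change shared by all genes does not show, and noise of single arrays weakens a correlation. Within these limits Top2 was only weakly related to Pol II across genes. Its change at the promoter correlated with the Pol II change over the gene with r = 0.095 (rho = 0.092) across 5387 genes, and over coding regions with r = -0.007. Heat-shock (0.50, percentile 99.96) and mating-type promoters (0.57, percentile 99.7) had more Top2 and ribosomal protein (-0.07, percentile 0) and meiotic promoters (-0.26, percentile 0.53) less. At heat-shock, mating-type and ribosomal protein genes this was the direction of the Pol II change. Ribosome biogenesis promoters, with lower Pol II over their genes, had a Top2 change of 0.15 (percentile 79.9). The highest promoters were SHP1 (1.57), SER3 (1.49), ABD1 (1.45), PRP5 (1.45) and XRN1, for an exonuclease of messenger RNA (1.37). The lowest were SMD1, for a splicing protein (-2.54), SRD1 (-2.27), SGM1 (-1.96), RRP6 (-1.85) and SPO11, which makes meiotic breaks (-1.77). RPO21 had a Top2 change of -1.29 at its promoter and TOP2 of -0.82. Along 2145 genes the Pol II ratio of the last part of the gene exceeded that of the first by 0.38, and the Top2 ratio was lower there by a difference of -0.45.

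The last pair of arrays compared H3 and Top2 of the double mutant directly with wild type, to see whether nucleosomes or Top2 shift at promoters. H3 was high at the promoters of phosphate-response genes (median 0.47, percentile 100), with PHO84 at 2.01, and of ribosomal protein genes (0.34, percentile 100), with RPS24B at 1.17. It was also high at heat-shock genes (0.31, percentile 99.8), and at glycolytic genes it was 0.31 (percentile 92.7), with PFK2 at 1.16. CCW12, for a cell wall protein, stood at 1.78. LEU2 stood at 1.84, a value that also holds its copy number, since this array has no input channel and LEU2 DNA was over-represented in the mutant input by 0.88. Among promoters present in both strains the lowest were CHA4 (-1.62), RAD26 (-1.50), FAR1 (-0.95) and TRX3 (-0.75). The promoter of HXT7 (-2.38) is missing from the double mutant, and the highest 5 promoters, YNR071C, YGL262W, HXT17, COS12 and MAN2, from wild type. Over coding regions H3 was high for ribosomal protein genes (0.37, percentile 100) and low for glycolytic genes (-0.12, percentile 0.92), although both lists had less Pol II in the double mutant. Across 5394 genes the H3 change at the promoter correlated with the Pol II change with r = -0.31 (rho = -0.264). By wild-type Pol II level the H3 change went from 0.02 to 0.17 over the 5 groups. The Top2 array had a weak red channel and a wide spread (SD 1.26 over promoters, median -0.56). Its ratios correlated with the Top2 difference of the arrays over input with r = 0.151 (rho = 0.134) across 5487 promoters, or with 0.417 with normexp background and 0.374 after loess.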

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

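The test of ribosomal protein genes against genes of like Pol II level, the test by scan day, the test by scaling and the test of the missing stretch of DNA were chosen after the results were seen.

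The change in Pol II in the double mutant differed from the sum of the changes in top1 and top2-ts at 323 genes, as tested with the interaction in limma, where the scan days of top1 and top2-ts cannot be told apart from the strains. By list, the median difference was -1.062 for ribosomal protein, 0.352 for heat-shock, 0.338 for general stress, -0.26 for ribosome biogenesis, -0.825 for histone and -0.205 for meiotic genes. The largest differences were 1.564 at BTN2, 1.33 at YHR007C-A, 1.236 at AGA1, 1.182 at FUN19, 1.171 at HPF1, -2.431 at RPL38, -2.133 at RPL26A, -2.059 at PDR18, -2.046 at YNR071C and -1.944 at RPL31B; PDR18 and YNR071C are missing from the wild-type and top1 inputs, so their values do not measure binding. Among genes named in advance it was -0.825 at HHT1, -0.914 at HHT2 and -0.802 at TOP1.

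Ribosomal protein genes fell by more than the rest in the double mutant, and weaker enrichment of every strongly bound gene was tested as a technical cause. Lists drawn from 180 other genes of like wild-type Pol II level had medians from -0.85 to -0.575, against -1.066 for ribosomal protein genes, which puts these at percentile 0. On these arrays they thus fell by more than other genes of like level. Members of the drawn lists were picked independently, while ribosomal protein genes moved together (estimated correlation 0.67). The percentile therefore does not measure the spread between arrays, and weaker enrichment was not excluded. A difference between scan days is argued against by the within-day medians, of which the higher was -0.862, and a scaling difference by the highest median under other scalings, -0.679. A loss of Pol II from these genes through the missing topoisomerases, through a slower growth of the double mutant, or through other differences between the strains remains open and was not tested.

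The input channel, which no comparison of the report uses as an outcome, differed between strains at a few genes: the range of the input signal over strains was 9.22 at YGL262W, 8.11 at COS12, 8.55 at PDR18, 8.32 at YNR071C, 8.33 at AIF1 and 3.12 at TOP1 on the log2 scale. The input of LEU2 was higher than in wild type by 0.878 in the double mutant and by 0.999 in top1.

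Pol II ratios over PDR18, AIF1 and YNR071C were higher in top1 than in wild type. In means over all arrays of a strain, the input signal of each of the 3 genes was lower in both strains than in the double mutant or top2-ts. The smallest of these gaps was 8.03 on the log2 scale, and single arrays can lie closer. This stretch may be absent from the DNA of the wild-type and top1 strains, where the ratio rests on signal near background. Cross-hybridization from a near copy is argued against, since 0% of their probes share a run of bases with another place. No biological explanation was tested.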

How the results depend on the processing

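The fits without moderation, without genes missing from an input, without chromosome VIII, with mitochondrial genes and with all upstream probes were chosen after seeing the data. With n = 2 arrays the counts moved more than the directions: of 1733 values of named genes under other settings 1516 kept direction and side of the threshold, 185 became weaker, 17 stronger and 15 reversed, and of 144 list values 137 kept both. The list values cover 4 settings alone: normexp background, equal spread, probes well above background and no genes missing from an input. Quantile scaling, outside them, turned called lists to 0.178 (ribosomal protein, top2-ts), -0.036 (glycolysis, top1) and 0.031 (ribosomal protein, Top2 in the double mutant). With 1 array left out, 391 of 508 gene values and 478 of 504 list values kept both; the lone array of a strain is then assumed to vary like the others. The number of arrays limits the precision, and the scaling moves the counts too. Where no reason is given, the cause was not tested.

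The counts of genes were as follows, for the double mutant, top1, top2-ts, the interaction, and Top2 in the double mutant and top1. A single fit of all 14 arrays gave 1843, 30, 1087 and 978 for Pol II, and for Top2 2908 in the double mutant and 3 in top1. Without moderation limma gave 284 (double), 0 (top1, 463 unadjusted), 0 (top2-ts, 1213), 0 (interaction, 1124), 1830 (Top2 double) and 0 (Top2 top1, 383). The scan day as a random block gave 22 for top1, 938 for top2-ts, 1485 for the interaction and 171 higher and 573 lower in the double mutant, where the fitted block correlation was negative. The fixed block, with a term for days E and F alone, gave 56 higher and 224 lower in top2-ts, 38 and 152 for the interaction, 7 and 2 in top1, and 68 and 8 for Top2 in top1. Promoters in place of coding regions gave 627 in the double mutant and 1 in top1, and coding regions in place of promoters gave 20 for Top2 in top1. Normexp background gave 6 in top1 and 0 for Top2 in top1 (375 unadjusted), equal spread gave 6, 0 (369 unadjusted) and 644 for the interaction, and quantile scaling gave 674 for the interaction and 1 for Top2 in top1. The median over probes gave 34 for Top2 in top1, and leaving out genes missing from an input, which tests fewer genes, gave 6 for Pol II in top1.

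With 1 array left out, the counts ranged from 322 (without double mutant replicate 1) to 1014 in the double mutant, from 3 (without top1 replicate 2) to 12 in top1, from 1 (without top2-ts replicate 2) to 380 in top2-ts, from 8 (without double mutant replicate 2) to 435 for the interaction, from 2689 to 3447 for Top2 in the double mutant and from 5 (without wild-type replicate 2) to 167 (without wild-type replicate 1) for Top2 in top1.

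Reversed single values were, with normexp background, -0.234 for TOP1 in top1 and 0.011 for PDR18 in the interaction. With promoters for Pol II they were -0.265 for TOP1 and -0.305 for PDR18 in top1, 0.061 for HHT1 in top2-ts, and 0.273 for PDR18 and 0.22 for TOP1 in the interaction. With coding regions for Top2 they were -0.296 for GAL10 and 0.252 for TOP1 in the double mutant and 0.885 for TOP1 in top1. In top1, Top2 at AIF1 was -0.269 with probes well above background and -0.136 in the series matrix, and at MAN2 it was -0.085, -0.103 and, with the authors' log2 ratios, -0.101; both are missing from the inputs, as is PDR18. Ribosomal protein genes in top2-ts had 0.037 under equal spread. In top1, with 1 array left out, heat-shock genes ranged from -0.005 (without wild-type replicate 1) to 0.247, short genes from -0.115 to 0.063 (without wild-type replicate 1), and meiotic genes were 0.024 without top1 replicate 2.

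Between the highest and the lowest group by wild-type level the change was -0.48, with -0.245 under equal spread and from -0.612 to -0.406 with 1 array left out. Between long and short genes it was 0.037, with -0.045 under equal spread and from -0.069 (without wild-type replicate 1) to 0.148 with 1 array left out, and -0.006 without double mutant replicate 1. The correlation of H3 and Top2 after H4 depletion was -0.43 with normexp background and -0.442 with the authors' log2 ratios, against -0.509, and that of the direct Top2 array 0.417 with normexp background and 0.374 after loess, against 0.151. Under the other settings Top2 at wild-type promoters minus coding regions stayed between 0.377 and 0.5, and its correlation with Pol II between 0.253 and 0.275. With 1 array left out these ranged from 0.309 to 0.492 and from 0.244 to 0.287. The correlation of Pol II and Top2 in rpb1-1 stayed between 0.069 and 0.11.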

Other observations

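The tests of chromosome VIII were written down before their results were seen.

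On the single rpb1-1 arrays, chromosome VIII was low along its whole length with both antibodies. Its median over all probes was -0.498 for Pol II and -0.227 for Top2 (log2 rpb1-1 over RPB1), and 11 of 11 windows of 50000 bp lay below 0 on both arrays. Probes between genes, where Pol II is sparse, gave -0.698 for Pol II and -0.117 for Top2, and chromosome VIII was below the next lowest chromosome by -0.13 or more on both arrays, so an extra copy of it in part of the RPB1 control cells is a candidate explanation. Uneven signal over the array surface is argued against, since the chromosome was low within each of 4 blocks of the array features on both arrays, with -0.235 as the highest difference from the other chromosomes. The shift differed between the antibodies, from -0.545 to -0.504 over these blocks for Pol II and from -0.262 to -0.235 for Top2. A difference in copy number would by itself shift both arrays alike, so it does not account for this gap. The fall is smaller than a full extra copy would give, no input was measured on these arrays, and a lower level in the rpb1-1 cells cannot be ruled out.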
